A study of Homo sapiens with 6 samples.

How the data were processed

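Poly(A)-selected RNA from cells of 2 pancreatic ductal adenocarcinoma (PDAC) lines was sequenced on an Illumina HiSeq, per the labels' protocols and the series' design text. The 6 libraries form 4 groups. The line named 90 in the labels has 1 library labelled NC and 2 labelled siALDOA, and PANC-1, an established human PDAC line, has the same numbers. The prefix si was read as small interfering RNA against ALDOA. What the name 90 and the letters NC stand for, and whether siALDOA 1 and 2 are different siRNAs or repeats of the same one, is not given in the sources used here. No label says that libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

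The authors deposited FPKM values (fragments per kilobase of gene and per M fragments, with M for mega) for each gene and library. Reads were handled with HISAT2 and featureCounts on the build hg38, per the submitters' processing notes; versions, settings, strand use and the gene lengths behind the values are not given in the sources used here. The table held 41769 rows, of which 1 had no gene name. Of the 41768 genes, 28 symbols had been turned into calendar dates and 4 rows shared a symbol with another row. Genes were used under the symbols of the table.

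FPKM values are not counts, but their low values keep a trace of depth. For microRNA, snoRNA and snRNA genes, value times RefSeq gene length fell on whole multiples of a step for 96.1% to 97.4% of values (multiples up to 8, tolerance 0.03 of a step). The steps correspond to 17.8 to 21.8 M fragments per library. A value of 3 fragments on a gene of 1 kb is then 0.14 to 0.17 FPKM. Counting error is therefore small for abundant genes and large for short RNAs. Gene lengths for the other genes are not part of the table, so fragment counts were not rebuilt and no count test was run.

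Values were analysed as log2(FPKM + 1), so fold changes of low genes are understated. Genes with a mean of at least 1 FPKM over the 6 libraries were tested, 12592 genes, of which 11129 are of type mRNA. The effect of siALDOA over both lines and the difference between the lines came from a limma fit (R 4.3.3, limma 3.58.1) with terms for line and for siALDOA, an intensity trend in the prior variance and 3 residual degrees of freedom. Effects within each line, and the difference between these effects, came from a fit of the 4 group means with 2 residual degrees of freedom. In that fit the lone NC library of a line is assumed to vary like the siALDOA libraries. A gene was called at a Benjamini-Hochberg adjusted p under 0.05.

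A set of 38 gene lists was written down before the data were examined, covering metabolism, stress, cell cycle, PDAC subtypes and markers of other cell types. Lists with at least 5 tested members (34 lists) were tested with limma's camera at a preset inter-gene correlation of 0.01, with camera at an estimated correlation and with fry, all two-sided, and adjusted over the lists. ALDOA was left out of the glycolysis list. A list's median was also set against 10000 random lists matched on mean level, and on mean level and GC content. GC content was that of the longest GENCODE v29 transcript of the symbol, found for 94.4% of the tested genes.

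The named genes follow a rule written before the data were examined. For siALDOA against NC these are ALDOA and ALDOC, then up to 12 called genes per direction whose 4 siALDOA libraries lie on the same side of the NC library of their line. Where fewer were called, the 6 smallest p-values per direction are given as values. For PANC-1 against 90 these are the 8 highest and the 8 lowest called genes. For a list, up to 4 called members with the largest change are named, or, with none called, the 2 with the smallest p. The genes of type mRNA named beside the short RNAs are an addition made after their values were seen. Some genes that the rule takes in are not reported here.

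The limma fits and the camera test at its preset correlation were tested on simulated log2 values made from the observed means and gene-wise spread. For the fits, 200 of the 12592 genes were changed. For siALDOA against NC over both lines, 10% of the genes changed by 1 log2 unit and 55% of those changed by 2 units were called, with 5 false calls. Within either line, and for the difference between the siALDOA effects of the lines, 0 of the changed genes were called at that spread. With the observed spread divided by 4, the fit over both lines called 89% and 96%. For PANC-1 against 90, 72% of the genes changed by 2 units and 84% of those changed by 4 units were called. An interferon list moved by 0.5 was called, and 0 of the other lists were. The simulated spread was drawn independently for each gene and library. It lacks the trend that the real libraries share, so it shows neither how camera treats correlated lists nor the power under that trend.

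Alternatives planned before the data were examined were other pseudocounts, filters, scalings, a fit without the trend, each library left out, a replicate block, each siALDOA number alone, other thresholds and a count test, which was not run. Corrections for GC content, a crossed block, mRNA genes alone and the omission of siALDOA library 1 of both lines were added after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.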

Results

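The transcriptomes of 2 PDAC cell lines, the line named 90 and PANC-1, were measured after treatment with siRNA against ALDOA. ALDOA encodes fructose-bisphosphate aldolase A, the glycolytic enzyme that splits fructose 1,6-bisphosphate. Each line had 1 NC library and 2 siALDOA libraries, called siALDOA 1 and siALDOA 2 after the numbers in the labels. Depth recovered from the values was 17.8, 19.5 and 19 M fragments for NC, siALDOA 1 and siALDOA 2 of the 90 line, and 20.6, 21.8 and 18.7 M for those of PANC-1. Between 11133 and 12687 genes per library reached 1 FPKM. Genes above 0 numbered 23356 in siALDOA 1 of PANC-1 and 19171 to 20371 in the other libraries.

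ALDOA was lower in all 4 siALDOA libraries than in the NC library of the same line. In the 90 line it stood at 726 FPKM in NC, at 262 in siALDOA 1 and at 318 in siALDOA 2, a mean of 39.9% ± 5.4 of NC (SD, n = 2). In PANC-1 it stood at 906 FPKM in NC, at 501 in siALDOA 1 and at 462 in siALDOA 2, a mean of 53.1% ± 3.1 of NC (SD, n = 2). The gene lies on chromosome 16 from 30064164 to 30070457 on the plus strand (GRCh38, GENCODE v29). Its log2 change over both lines was -1.12 (SE 0.160), the smallest limma p of the 11129 mRNA genes (unadjusted p = 9.07e-04), but it did not pass the adjustment over all genes (adjusted p = 1). With the control permuted within each line, 9 choices are possible, and the observed choice gave the largest change (exact permutation p = 0.111, two-sided, the smallest this design allows). ALDOC, the gene of aldolase C, was at 35.3 FPKM in NC and at 19.95 and 29.5 in the siALDOA libraries of the 90 line. In PANC-1 it was at 3.15 in NC and at 2.08 and 1.86.

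**Figure D1:**
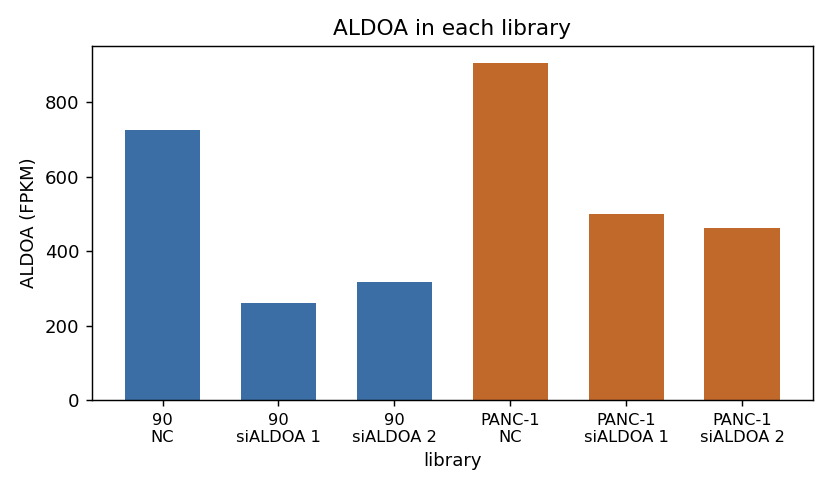
ALDOA level (FPKM, bars from 0) in each of the 6 libraries, blue for the 90 line and orange for PANC-1. Each siALDOA library lies below the NC library of its line, at 262 and 318 against 726 FPKM in 90 and at 501 and 462 against 906 FPKM in PANC-1.

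The comparison of siALDOA with NC over both lines asks which other transcripts changed with the loss of ALDOA. No gene passed the limma test at an adjusted p under 0.05, with 0 of 12592 genes called and 43 at an unadjusted p under 0.05. Independent genes and libraries would give 630 by chance, but these libraries share a trend, and with another library of each line, or of 1 line, taken as control the number ran from 33 to 5687, with 2770 called for siALDOA 1 of 90 and siALDOA 2 of PANC-1 as controls and 0 for the other choices. Among mRNA genes, looked at apart after their values were seen, those with the smallest p on the higher side included MX2 and OASL, both interferon-induced antiviral genes, DHX58, a sensor of viral RNA, and PODXL, which encodes the sialomucin podocalyxin. MX2 was at 12.2 FPKM in NC and at 22.3 and 22.5 in siALDOA libraries of the 90 line, and at 16.8 against 22.4 and 18.4 in PANC-1 (log2 change 0.54, SE 0.193). OASL was at 27.4 against 34.6 and 52.1 in 90 and at 0.418 against 1.25 and 1.05 in PANC-1 (log2 change 0.61, SE 0.222). On the lower side were SERPINB6, an intracellular protease inhibitor (log2 change -0.50, SE 0.133), TMA7 (-0.39, SE 0.105) and ASMTL (-0.95, SE 0.213), none past the test. SERPINB6 was at 20.3 FPKM in NC against 13.7 and 14.5 in 90, and at 24.9 against 17.9 and 16.4 in PANC-1.

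Several of the smallest p-values belonged to short RNAs that overlap other transcripts, so their values are uncertain in poly(A) libraries. On the higher side the 6 smallest were MIR939, SNORD83A, MIR3191, MIR3190, MIR7705 and MIR3614. MIR939 was listed at 0 in both NC libraries and at 1.67 to 4.38 FPKM in the siALDOA libraries. On the lower side MIR4722 was at 3.75 and 4.04 FPKM in the NC libraries and at 0 to 0.89 in the siALDOA libraries, and SNORA10 had a log2 change of -0.65 (SE 0.147). Within the 90 line 0 genes were called (33 at an unadjusted p under 0.05), and within PANC-1 0 were called (21 at an unadjusted p under 0.05). Without siALDOA 1 of both lines, an alternative added after seeing the data, limma called 17 genes, 9 higher and 8 lower, and ALDOA was not among them (log2 change -1.08, adjusted p = 0.152). Only 4 of the 17 were mRNA genes, TOP2A, KIF5B, KTN1 and ANLN, all called higher, and the others were short RNAs. In the left-out libraries these mRNAs lay above NC in siALDOA 1 of 90, TOP2A at 86.2 FPKM against 3.98, and below NC in siALDOA 1 of PANC-1, TOP2A at 3.25 against 35.1. The fit behind these calls keeps only NC and siALDOA 2 of each line. It has fewer residual degrees of freedom than the 3 of the main fit, so its spread is poorly estimated.

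The siALDOA libraries of a line differed 2-fold from each other in more genes than either did from NC. Between siALDOA 1 and siALDOA 2, 2649 genes differed at least 2-fold in the 90 line and 2414 in PANC-1, against 2022 and 219 between NC and siALDOA 1 and 2 in 90, and 1428 and 512 in PANC-1. Genes of low GC content were higher in siALDOA 1 of the 90 line and in siALDOA 2 of PANC-1 and lower in siALDOA 1 of PANC-1. In the eighth of genes with the lowest GC content (25% to 39.6%) the median log2 change from NC was 1.40 and 0.12 in the 90 libraries 1 and 2, and -1.02 and 0.56 in the PANC-1 libraries 1 and 2. A first axis that follows this held 83.9% of the variance within lines.

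**Figure D2:**
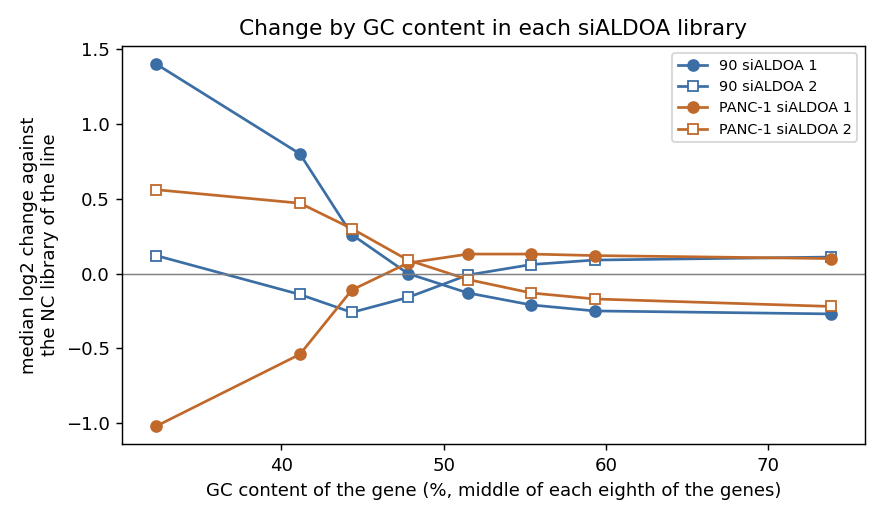
Median log2 change of each siALDOA library against the NC library of its line (vertical axis) over eighths of the tested genes ordered by GC content (horizontal axis, percent). In the eighth of lowest GC content the medians run from -1.02 in PANC-1 siALDOA 1 to 1.40 in 90 siALDOA 1.

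As groups, the genes of the type I interferon response were higher with siALDOA, and genes of the ribosome and of oxidative phosphorylation were lower, by camera at its preset correlation. With an estimated correlation none of these calls held (adjusted p = 0.765 for interferon, 0.81 for the ribosome and 0.765 for oxidative phosphorylation). The interferon list had a median log2 change of 0.58, with 21 of its 22 tested members above 0 (camera adjusted p = 3.28e-16). Cytosolic ribosomal protein genes had a median of -0.20 with 0 of 33 above 0 (camera adjusted p = 3.28e-16), nuclear genes of oxidative phosphorylation a median of -0.18 with 1 of 28 above 0 (5.95e-11), and mitochondrially encoded mRNAs a median of -0.09 with 1 of 13 above 0 (3.77e-03). No member of these 4 lists passed the gene test, and 0 passed when adjusted over the list alone. The call of the mitochondrially encoded mRNAs did not hold with an estimated correlation either (adjusted p = 0.81). In limma's fry, which asks whether a list's genes move 1 way on balance, the interferon list had an adjusted p = 0.858.

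The interferon genes stood out in the 90 line. Their median against NC was 0.80 in siALDOA 1 and 0.84 in siALDOA 2, and 22 of 22 members were above 0 in siALDOA 2. Among 10000 random lists matched on level and GC content, these medians were at percentile 100 in each library. Percentile 100 in 1 library was not particular to this list. G2/M genes were at 100 in siALDOA 1 and 81.6 in siALDOA 2, cholesterol genes at 97.7 and 100, and lysosome genes at 68.4 and 100. ISG15, a ubiquitin-like protein induced by interferon, was at 1234 FPKM in NC and at 1704 and 2778 in the siALDOA libraries. IFI6 was at 745 against 1108 and 1820, MX1 at 40.9 against 70.7 and 93.4, and OAS1 at 53.1 against 82.6 and 115. IFI44 was at 8.77 against 94.5 and 27.9, and these 5 genes were singled out after their values were seen. In PANC-1 the list medians were 0.10 and 0.08. ISG15 was at 91.3 FPKM in NC and at 90.4 and 61.2 there. Each line has a single NC library, so every change within a line rests on it.

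Ribosomal and oxidative phosphorylation genes had their lowest medians in siALDOA 1 of the 90 line and siALDOA 2 of PANC-1, the libraries in which genes of low GC content were highest. Ribosomal protein genes had medians of -0.36 in siALDOA 1 of the 90 line and -0.38 in siALDOA 2 of PANC-1, but 0.01 in siALDOA 2 of the 90 line and -0.06 in siALDOA 1 of PANC-1. Genes of oxidative phosphorylation had medians of -0.25, -0.01, -0.08 and -0.31 in siALDOA 1 and 2 of the 90 line and siALDOA 1 and 2 of PANC-1. The members with the smallest p were RPS23 (log2 change -0.26, SE 0.110) and RPS6 (-0.24, SE 0.125) of the ribosome and NDUFA1 (-0.24, SE 0.120) and NDUFA4 (-0.25, SE 0.130) of respiratory complexes. After a correction of the GC trend the ribosomal and oxidative phosphorylation medians over both lines were -0.18 and -0.18, past camera (adjusted p = 3.56e-08 and 2.81e-06). They were smaller after quantile normalization (-0.08 and -0.10) and as TPM (-0.13 and -0.11), past camera in each case. Without siALDOA 1 of the 90 line the ribosomal median over both lines was -0.12, and without siALDOA 2 of PANC-1 it was -0.13, past camera in each case. The mitochondrially encoded list lost its call after quantile normalization (camera adjusted p = 0.911, median 0), after scaling by the median ratio (0.0504, median -0.12) and as TPM (0.0503, median -0.02). It also lost it without siALDOA 1 of 90 (-0.06), siALDOA 2 of 90 (-0.13) or siALDOA 2 of PANC-1 (-0.05). The glycolysis list without ALDOA had a median of -0.09, with 2 of 20 members above 0, and did not pass (camera adjusted p = 0.107). In it, LDHB had a log2 change of -0.41 (SE 0.313) and GAPDH of -0.17 (SE 0.217). Its medians were -0.35 and 0.08 in the 90 libraries and 0.11 and -0.20 in the PANC-1 libraries. The other 29 lists tested, among them hypoxia, the TCA cycle, the pentose phosphate pathway and apoptosis, did not pass either (lowest camera adjusted p = 0.115).

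**Figure D3:**
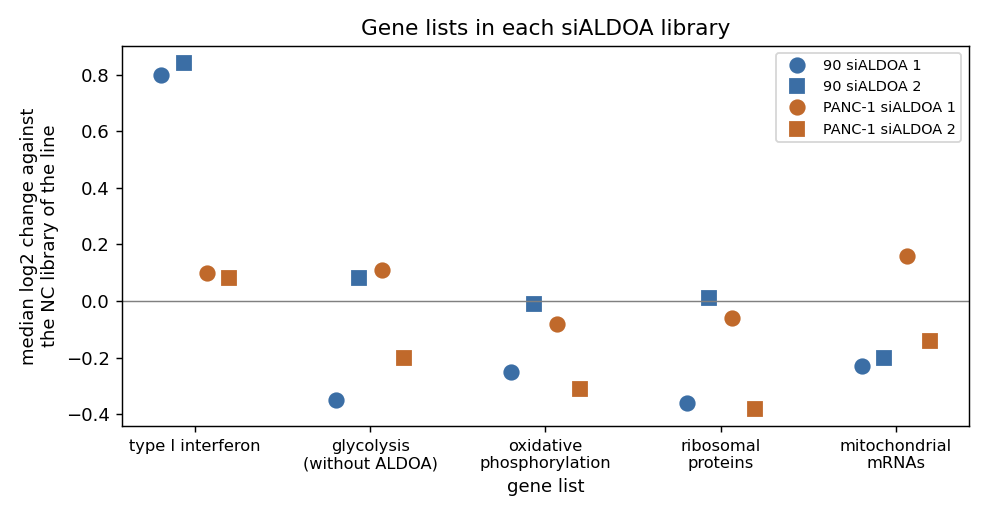
Median log2 change against the NC library of the line (vertical axis) for 5 gene lists (horizontal axis) in each siALDOA library, blue for 90 and orange for PANC-1, circles for number 1 and squares for number 2. The interferon list is at 0.80 and 0.84 in the 90 libraries and at 0.10 and 0.08 in the PANC-1 libraries.

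The difference between the effects in both lines was tested as an interaction. No gene passed (0 called by limma, 24 at an unadjusted p under 0.05). Of the 34 lists, 2 differed by camera. The effect on interferon genes was lower in PANC-1 than in 90, with a median difference of -0.77 (camera adjusted p = 1.08e-09), and with the interferon median at 0.84 in the 90 line (camera adjusted p = 5.74e-23, and 0.265 with an estimated correlation) and at 0.13 in PANC-1 (0.237). Mitochondrially encoded mRNAs differed by 0.26 (camera adjusted p = 3.16e-03). With an estimated correlation neither held, the lowest adjusted p being 0.619. Across the 12592 genes, which are not independent replicates, the log2 changes of the lines correlated at r = -0.39 (Pearson) and rho = -0.19 (Spearman). The sign rested on 1 library: without siALDOA 1 of PANC-1 the correlation was 0.51, and without siALDOA 2 of PANC-1 it was -0.74. Within the 90 line 7 lists passed camera and within PANC-1 3 did, none with an estimated correlation (lowest adjusted p = 0.265 in 90 and 0.965 in PANC-1). In 90 these included serine, glycine and one-carbon metabolism (median -0.24, 0 of 10 above 0, camera adjusted p = 6.12e-03), with medians of -0.21 in siALDOA 1 and -0.20 in siALDOA 2. Homologous recombination and Fanconi genes also passed in 90 (median 0.61, camera adjusted p = 0.031), but their median was 1.34 in siALDOA 1 and 0.02 in siALDOA 2. The glycolysis list passed there as well (median -0.13, camera adjusted p = 0.0379), with medians of -0.35 in siALDOA 1 and 0.08 in siALDOA 2. In PANC-1 basal-like subtype genes passed (median 0.16, camera adjusted p = 7.39e-03), with medians of 0.34 in siALDOA 1 and 0.05 in siALDOA 2. KRT6A of that list was at 0.415 FPKM in NC, 3.64 in siALDOA 1 and 1.002 in siALDOA 2, and KRT17 at 0.291, 1.48 and 0.345.

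PANC-1 and the 90 line differed in many genes. The comparison takes NC and siALDOA libraries together, since 1 NC library per line allows no test of the basal state alone. Of 12592 genes, limma called 4882, with 2567 higher and 2315 lower in PANC-1, and 3184 of them differed at least 2-fold. Without 90 NC 2424 genes were called, and without PANC-1 NC 2422. The median over all tested genes was 0.13 as deposited and 0.02 after scaling by the median ratio. The share of called genes that were higher in PANC-1 was 52.6% as deposited, 43% of 3514 called genes after that scaling and 48.5% of 6191 after the GC correction, so which direction held more genes turned with the scaling. Among the 8 lowest genes were the keratins KRT5 and KRT6A. KRT5 was at 618 to 791 FPKM in the 90 libraries and at 0.463 to 3.68 in PANC-1 (log2 difference -8.28, SE 0.445, adjusted p = 2.91e-04). KRT6A (-8.18, SE 0.413), SLPI, a secreted protease inhibitor (-7.76, SE 0.357), LCN2 or lipocalin 2 (-7.71, SE 0.396), ALDH3A1 (-7.87, SE 0.345), ANXA8 (-7.86, SE 0.361), IFI27 (-9.25, SE 0.506) and BST2 or tetherin (-7.67, SE 0.286) completed the 8 lowest. KRT6A and ANXA8 have near-identical paralogs, so their values are uncertain. In siALDOA 1 of PANC-1 several of these genes stood above its other libraries, IFI27 for example at 9.73 FPKM against 1.73 and 2.34.

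Genes nearly restricted to PANC-1 included LDHB, the B subunit of lactate dehydrogenase, at 198 to 394 FPKM against 0.239 to 0.987 in 90 (log2 difference 7.59, SE 0.295, adjusted p = 1.82e-04). The others of the 8 highest were PPP1R14A, an inhibitor of myosin phosphatase (8.44, SE 0.176), the metallothionein pseudogene MT1L (8.32, SE 0.198), the chemokine CCL2 (6.73, SE 0.191), PEBP1 (6.71, SE 0.182), CD70 (6.38, SE 0.196), the Notch ligand DLL3 (6.35, SE 0.182) and BASP1 (6.31, SE 0.186). MT1L shares sequence with other metallothioneins and is uncertain. Glycolysis genes went both ways, with 6 of 20 higher and 6 lower (7 higher and 8 lower adjusted over the list alone). The glucose transporter SLC2A1 (-1.78, SE 0.222), hexokinase HK2 (-1.48, SE 0.192) and PFKFB3 (-1.36, SE 0.188) were lower in PANC-1.

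By gene list, PANC-1 was lower in tested markers of both PDAC subtypes, epithelium, interferon and NF-kB, by camera at its preset correlation. With an estimated correlation none of these 5 calls held (adjusted p = 0.358 for each), and that of NF-kB was also lost after the GC correction (camera adjusted p = 0.0586), at the same median of -1.22. In fry, which does not compare a list with other genes, the 5 lists passed, with adjusted p from 1.31e-04 for NF-kB to 1.63e-03 for interferon. Basal-like subtype genes had a median difference of -5.53 with 15 of 16 lower (KRT6A, KRT17, CST6 and KRT7; 15 adjusted over the list alone). KRT6A, KRT17 and CST6, at 0.291 to 3.64 FPKM in PANC-1, passed the filter only through their levels in 90. KRT7 was at 6.24 to 11.5 FPKM in PANC-1. Members of the other lists, among them OAS1, RAB25 and IL1B, also passed only through 90. Genes low in both lines were not tested, so the medians leave them out. Interferon genes had a median of -3.44 with 16 of 22 lower (17 adjusted over the list alone), among them IFI27, IFI6, OAS2 and OAS1. Epithelial junction and keratin genes had a median of -1.73, with 14 of 22 lower and 2 higher (15 and 2 adjusted over the list alone), including KRT7 (-6.96, SE 0.276), RAB25 and the E-cadherin gene CDH1 (-4.00, SE 0.189). Classical subtype genes had a median of -2.74, with 5 of 7 lower and 1 higher (5 and 1 adjusted over the list alone). GATA6 (-2.74, SE 0.176) and CEACAM6 (-4.78, SE 0.257) were lower. Only 7 of the list's 20 genes were tested, and GATA6, CEACAM6, ANXA10 and VSIG2 passed the filter only through their levels in 90. AGR2 ran the other way, at 78, 33.8 and 70.1 FPKM in PANC-1 against 17.5, 23.9 and 15.6 in 90. As TPM the classical median was -1.63 (camera adjusted p = 0.0128). NF-kB targets had a median of -1.22, with 11 of 18 lower and 3 higher (13 and 3 adjusted over the list alone). IL1B (-6.84, SE 0.269) and CCL20 (-4.45, SE 0.327) were lower and CCL2 higher.

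Smaller shifts were found by camera in genes of protein synthesis and respiration, and none held with an estimated correlation (lowest adjusted p = 0.358). Genes of MYC and ribosome biogenesis were higher in PANC-1 (median 0.78, 8 of 22 higher and 0 lower, the same numbers adjusted over the list alone), led by FBL, the nucleolar methyltransferase fibrillarin (4.62, SE 0.156), and RRP12 (1.78, SE 0.192). Cytosolic ribosomal protein genes had a median of -0.44, with 12 of 33 lower and 2 higher (14 and 3 adjusted over the list alone), RPS6 at -2.17 (SE 0.118) and RPS16, in the other direction, at 4.01 (SE 0.203). Ribosomal protein genes have many processed pseudogenes, so their values are uncertain. Chaperones and other genes of the unfolded protein response had a median of -0.56, with 6 of 18 lower and 1 higher (the same numbers adjusted over the list alone), including XBP1 (-1.76, SE 0.134). Oxidative phosphorylation genes had a median of 0.36, with 8 of 28 higher and 1 lower (the same numbers adjusted over the list alone), including NDUFA1 (1.69, SE 0.113). Over all 12592 tested genes 2567 were called higher and 2315 lower, so counts of called members do not by themselves set these lists apart. In fry ribosome biogenesis (adjusted p = 5.95e-04), the unfolded protein response (0.0255) and oxidative phosphorylation (0.0223) passed and ribosomal proteins did not (0.181). All 9 lists passed camera, with adjusted p from 9.82e-11 for the basal-like list to 0.0471 for oxidative phosphorylation. The ribosomal and unfolded protein response calls were lost when each library was scaled by the median ratio (camera adjusted p = 0.084 and 0.0815), although their medians were then -0.57 and -0.68. That of oxidative phosphorylation was lost too (0.166), at a median of 0.23. Quantile normalization also cost the ribosomal list its call (0.0594, median -0.24). After the GC correction each of these calls was lost. The ribosomal list was then at -0.47 (camera adjusted p = 0.0586), the unfolded protein response at -0.70 (0.0586) and oxidative phosphorylation at 0.20 (0.142).

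**Figure D4:**
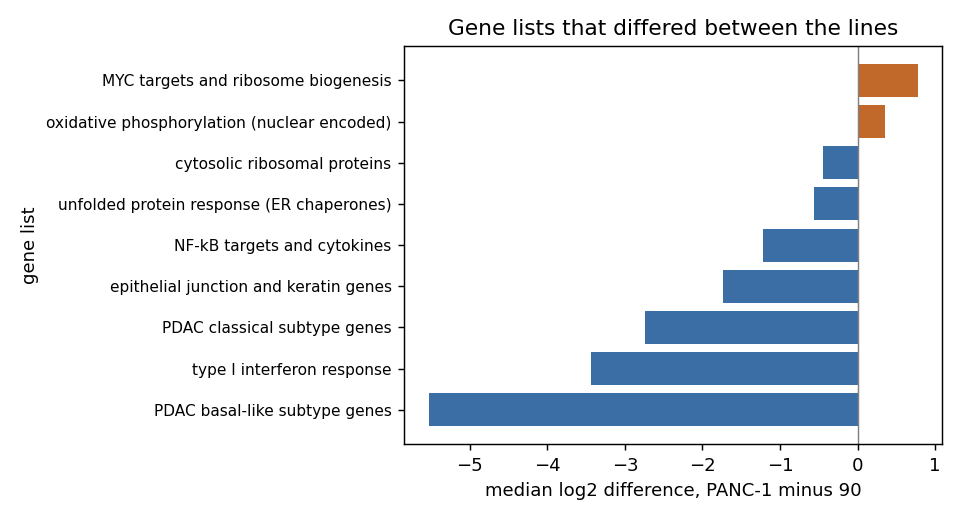
Median log2 difference, PANC-1 minus 90 (horizontal axis), of the 9 gene lists past camera (vertical axis), blue for lower and orange for higher in PANC-1. Medians run from -5.53 for basal-like subtype genes to 0.78 for MYC targets and ribosome biogenesis.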

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

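The tests of GC content, of the reagent numbers, of PANC-1 levels, of siRNA delivery and of carry-over were chosen after the results they bear on were seen. The groups hold at most 2 libraries each, too few for a test of single outlying libraries.

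A camera test of the difference between the siALDOA effects of the lines picked out 2 gene lists, neither of which held with an estimated correlation (adjusted p = 0.619 for interferon and 0.934 for mitochondrially encoded mRNAs). The siALDOA effect on type I interferon genes was lower in PANC-1 than in the 90 line (median difference -0.77), and that on mitochondrially encoded mRNAs was higher (median difference 0.26). Medians of 2 further lists lay on opposite sides of 0 in all libraries of each line, and their difference did not pass the test. These were G1/S and DNA replication genes (-0.11 and -0.08 in 90, 0.09 and 0.09 in PANC-1, median difference 0.07, camera adjusted p = 0.288) and MYC targets and ribosome biogenesis (-0.21 and -0.03 in 90, 0.04 and 0.05 in PANC-1, median difference 0.10, camera adjusted p = 0.758).

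GC content alone does not account for the interferon pattern in the 90 line. The list's median there was 0.89 after the GC correction, against 0.84 before. A trend shared by the libraries remained after it (r = 0.69, crossed numbers). Before the correction, DDX58, IFIT1, IFIT2 and IFIH1, singled out after their values were seen, went with the first axis only in part. They lay above NC in siALDOA 1 of 90 and siALDOA 2 of PANC-1, and below NC in siALDOA 1 of PANC-1. In siALDOA 2 of 90, near NC on the first axis (-0.28 against -0.3), the list's median was 0.84. These genes lay above NC there too, DDX58 at 5.67 FPKM against 2.46 and IFIT1 at 29.2 against 14.4. Whether they follow the trend left after the correction was not tested. Low levels in PANC-1 did not hide an equal response: the 7 list genes at 5 FPKM or more in its NC library had a median change of 0 in PANC-1 (0.09 in siALDOA 1, -0.14 in siALDOA 2) and of 0.73 in the 90 line. An effect of siRNA delivery or sequence and an effect of ALDOA loss cannot be told apart, because the make of NC is not known and only 2 siALDOA libraries of the line exist, whose list medians differed by 0.04. All of it rests on 1 NC library per line.

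The difference between siALDOA 1 and 2 followed GC content in opposite directions in the lines, with Spearman's rho of -0.79 in 90 and 0.76 in PANC-1 across genes. Reagents numbered alike in both lines are argued against as its source: the differences 1 minus 2 correlated at r = -0.86 between lines. A GC bias of library preparation may account for much of it: after the GC correction, genes that differed 2-fold fell from 2577 to 659 in 90 and from 2360 to 1152 in PANC-1. Reagents with crossed numbers stay open, as the difference 1 minus 2 in 90 and 2 minus 1 in PANC-1 still correlated at r = 0.69 after the correction, which a bias beyond GC content would also give.

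Transcripts of the 90 line appeared at a low level in siALDOA 1 of PANC-1. Of 21 mRNA genes at 100 FPKM or more in every 90 library and under 1 FPKM in PANC-1 NC, 100% were above NC in siALDOA 1, at a median of 0.411% of their 90 level (quartiles 0.374% and 0.46%). Induction by the loss of ALDOA is argued against, since the median excess in siALDOA 2 was 6.58% of that in siALDOA 1. A carry-over of RNA or reads from a 90 library is a candidate explanation, and it bears on IFI27, KRT5 and the basal-like genes KRT6A, KRT17, CST6 and LY6D in PANC-1.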

How the results depend on the processing

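The GC corrections, the crossed block, the mRNA-only fit and the omission of siALDOA 1 of both lines were chosen after seeing the data. Without the NC library of a line, a value over both lines is that of the other line alone. The log2 change of ALDOA kept its direction in all 22 alternatives (-1.33 to -0.91, both ends from a single line) and did not pass in any (adjusted p 0.152 to 1). The count of 0 genes for siALDOA over both lines held in 25 of 26, the exception being 17 genes without siALDOA 1 of both lines. Each siALDOA number against NC within the fit of all 6 libraries, whose spread includes both numbers, gave 0 calls, number 2 included. The difference between the siALDOA effects of the lines gave 0 in all 19. Without a filter on low values, 38 genes were called within the 90 line and 49 within PANC-1, all with a mean under 1 FPKM, genes that the filter removes. Lists called for siALDOA were 4, but 7 at a mean of at least 5 FPKM and 9 after quantile normalization. Leaving out 1 library gave 3 to 7 such lists, with 7 without siALDOA 1 of the 90 line and 7 without PANC-1 NC. The interferon list lost its call only without 90 NC, where 0.13 is the value of PANC-1 alone, as 0.84 without PANC-1 NC is that of 90 alone. In PANC-1 alone it passed only with a pseudocount of 0.1 FPKM (0.19, camera adjusted p = 0.0368). Ribosomal (-0.28 to -0.08) and oxidative phosphorylation genes (-0.22 to -0.10) kept theirs in all 22. The mitochondrially encoded list kept its call in 10 of 19 and ranged from -0.23 to 0.01 with 1 library left out, above 0 without 90 NC, where PANC-1 alone is left. The glycolysis list passed in 4 of 22, without siALDOA 2 of 90 (-0.16), PANC-1 NC (-0.13) or siALDOA 1 of PANC-1 (-0.16) and with the crossed block (-0.09).

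The correlation of the effects between the lines ran from -0.74 to 0.51 with 1 library left out, above 0 only without siALDOA 1 of PANC-1. For PANC-1 against 90, 2422 to 4110 genes were called with 1 library left out, fits that all hold fewer libraries. The count was 2424 without 90 NC and 2422 without PANC-1 NC. The count was 8048 with the GC index of each library as a term. Lists between the lines fell from 9 to 5 after the GC correction and to 5 with the replicate block and the GC correction together. The cause of these changes was not tested. Of the 55 genes named for this comparison, none reversed, and 954 of 984 values kept their call.

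Replicate block: numbers 1 and 2 occur in both lines, and their deviations correlated at r = -0.86, so the main trend did not follow the numbers. Whether the numbers pair the libraries by reagent is not settled by this, because that trend could mask it. With the number as a block, 0 genes were called for siALDOA and 3258 for PANC-1 vs 90, and the lists called were 4 and 8. A crossed block called 0 genes for siALDOA and 7594 between the lines, with 7 and 10 lists. Without an NC library, its line gives no within-line value, difference or correlation; the same holds for the within-line fits without siALDOA 1 of both lines, which leave no spread. A count test was not run because gene lengths are not part of the table. At 17.8 to 21.8 M fragments, values under 0.14 to 0.17 FPKM rest on under 3 fragments per kb.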

Other observations

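The test of the neighbours on chromosome 19 was written before their values were seen but after PPP1R14A, DLL3, FBL and RPS16 had drawn attention to the stretch, and the windows were compared after that.

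Genes outside the 9 called lists also separated the lines, although their lists did not pass camera. The counts below stand beside 2567 genes called higher and 2315 called lower of all 12592 tested. Of 16 NRF2 targets, 6 were lower and 2 higher in PANC-1. The aldo-keto reductases AKR1C3 (log2 difference -4.48, SE 0.231), AKR1C2 (-4.24, SE 0.168) and AKR1C1 (-3.82, SE 0.198), close paralogs whose values are uncertain, were lower, and HMOX1, heme oxygenase 1, was higher (2.96, SE 0.298). Of 23 integrin and focal adhesion genes 5 were lower and 7 higher (list not past camera, adjusted p = 0.776). Among the largest changes, LAMB3 was at -7.26 (SE 0.261), ITGB4 at -5.61 (SE 0.203) and LAMA3 at -5.39 (SE 0.434). Of 15 tested mesenchymal genes, 8 were higher and 5 lower, with TAGLN (-5.06, SE 0.193), SNAI2 (-4.40, SE 0.261) and FN1 (-3.06, SE 0.161) among the lower. Hypoxia targets were split as well, 4 of 17 higher and 4 lower, with BNIP3 (5.44, SE 0.187), ANGPTL4 (4.89, SE 0.225) and ADM (3.53, SE 0.179) higher and EGLN3 (-2.47, SE 0.196) lower. In serine synthesis PSAT1 was higher (5.06, SE 0.164) and PHGDH lower (-2.24, SE 0.201). Lists of fibroblast, immune and endothelial markers had 2, 2 and 3 tested members and acinar and endocrine markers 0, too few for a list test.

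PPP1R14A, DLL3, FBL and RPS16, all named as higher in PANC-1, lie within 1.6 Mb of chromosome 19 (38251237 to 39846414, GRCh38, GENCODE v29). The other 31 tested mRNA genes of that span had a median log2 difference of 2.80, with 29 called higher and 1 called lower. PAF1 (4.76, SE 0.154), TIMM50 (5.12, SE 0.179), SUPT5H (3.65, SE 0.184) and PAK4 (2.80, SE 0.191), singled out after their values were seen, were among the higher genes. In the 1 Mb on either side the median over 24 genes was 0.64. Of 355 windows of 2 Mb with at least 10 genes, 1 had a median as high, at 3.16, a window of chromosome 19 that overlaps this span. As a hypothesis, this stretch may be present in more copies in PANC-1 than in 90, a change that neighbouring genes would share; copy number itself was not analysed here. FBL leads the ribosome biogenesis list, and RPS16 runs against the ribosomal list.

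The comparison of PANC-1 with 90 called 4882 genes, and the other splits of the 6 libraries into 3 and 3 called at most 0. Only 10 splits exist, of which 1 called as many, so the share cannot go below 0.05.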
